A study of Rattus norvegicus with 12 samples.

How the data were processed

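RNA of H9c2(2-1) rat myoblasts was sequenced in 12 libraries: 3 each of control cells, cells deprived of glucose (GD) for 36 h, and cells deprived in the presence of 100 or 200 µM empagliflozin. Per the labels, total RNA was extracted with TRIzol and treated with DNase before library preparation with Illumina protocols. The labels state no serum for the deprived groups, no batch or date, no solvent for the drug or the GD cells, and not whether libraries of a group are separate cultures.

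The deposited table holds 1 column of TPM (transcripts per 1000000) per library for 35966 gene symbols, with 2 decimals, made by the authors. The submitters' processing notes name HISAT2 and StringTie; their versions, the genome build, the annotation and the strand setting are not given in the sources used here. The unit is not stated and was taken from the values: the columns sum to 946400.5 to 981389.8, close to the 1000000 of complete TPM, and short, abundant ribosomal protein transcripts lead them, as values per transcript length with a common total would have it. TPM keep no record of read numbers, so depth is unknown, counting intervals were not computed, and a value of 0 means listed at 0. The plan made before the data were examined foresaw either counts or a normalized unit, and its branch for normalized values was followed. The plan also fixed the groups, the comparisons, the filter, the test, the gene lists, the naming rule and the alternatives, apart from those named below as chosen after seeing the data.

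Genes with at least 1 TPM in at least 3 libraries were tested, which left 12314; 13647 were 0 in every library. Values were analysed as log2(TPM + 1) with limma-trend (limma 3.58.1 in R 4.3.3), with 1 mean per group, all 12 libraries in 1 model and Benjamini-Hochberg adjustment over all genes tested within each comparison, at an adjusted p under 0.05. Tests are two-sided. The comparisons were GD against control, 100 µM against GD, 200 µM against GD, 200 against 100 µM, and each dose against control. Replicate numbers were not used as a factor, since no label says that they mark shared cultures.

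Of the 34 gene lists that were fixed, 33 had at least 3 tested members and were analysed: integrated stress response, ER chaperones, hexosamine pathway, glycolysis, glucose-sensor targets, pyruvate dehydrogenase and citric acid cycle, nuclear-encoded respiratory chain, cholesterol, fatty acid synthesis, fatty acid oxidation, autophagy, lysosome, sodium handling, p53 targets, apoptosis and necroptosis, DNA replication, mitosis, ribosomal proteins, ribosome biogenesis, NRF2-type antioxidant genes, inflammation, interferon-stimulated genes, extracellular matrix, contractile and YAP-type targets, hypoxia, heat shock, FOXO and atrophy genes, immediate-early genes, and markers of skeletal muscle, cardiac muscle, fibroblasts, endothelium and leukocytes. The genes of the mitochondrial genome were not analysed here. Some genes stand in more than 1 list. Each list was compared with all other tested genes by camera of limma with a preset inter-gene correlation of 0.01, adjusted over the 33 lists. A gene of a list is counted as risen or fallen at an adjusted p under 0.05 over all genes tested, and a further count is adjusted over the list alone. With the correlation estimated from the libraries, no list was called in any comparison. The rotation test fry, which asks whether the genes of a list move on balance one way, was run beside it.

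Genes were named by a rule. In each of the 4 main comparisons these were the 6 highest and 6 lowest log2 fold changes among genes that passed, whose groups did not overlap, with an established symbol and a mean of at least 1 TPM. To these come the 3 members with the smallest p of each list that passed, the member with the smallest p of other lists discussed, and a fixed set throughout, of which Slc5a1, Slc5a2, Becn1, Sqstm1, Map1lc3b, Txnip, Ddit3 and Slc2a1 are given. For reversal these were the 6 genes with the largest change by deprivation among those that changed in the opposite direction at both doses. Values of a named gene may be given in other groups too. Some genes that the rule names are not reported here.

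Reversal was counted among genes changed by deprivation as those changed in the opposite direction by the drug against GD. The share undone is the part of the difference between GD and control, on the log2 scale, by which the drug group moved toward control; its median over these genes is given. As both contrasts hold the same 3 GD libraries, the counts, correlation and covariance stand beside means of 100 simulations without a drug effect and beside the overlap that lists drawn independently would have.

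The alternatives were quantile normalization, rescaling to a common total, no filter and a filter of 5 TPM, a pseudocount of 0.1, limma without trend, limma with array weights, a fit of the 2 compared groups alone, replicate number as an added term, an adjusted p under 0.01, a 2-fold minimum, estimated correlation and fry for the lists, and leaving out each library in turn. Median-of-ratios scaling and leaving out ribosomal protein and ferritin genes were added after seeing the data. A library left out leaves 2 in its group, whose spread is pooled with the other groups by the model.

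The fitting steps were tested on simulated data with the real means and spreads, all 12314 genes and genes drawn as independent. In each comparison 66 or 67 genes were changed at each size of change, up or down, and the others were not shifted. Of genes simulated with a log2 change of 1, 85.1% were recovered for GD against control, 70.1% for 100 µM against GD, 70.1% for 200 µM against GD and 79.1% between the doses. With a change of 0.5 the shares were 43.3%, 31.3%, 40.3% and 34.3%, and 11, 10, 5 and 5 genes without a simulated change were called. These values hold for few changed genes, whereas 1597 to 10042 were called in the real comparisons, so they do not give the power there. Figures were drawn with matplotlib 3.10.9 and tables prepared with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.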

Results

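The data are gene expression values from RNA-seq of total RNA of H9c2(2-1) cells, a rat myoblast line that was derived from embryonic heart. The 12 libraries form 4 groups of 3. Control cells grew in high-glucose medium with 10% serum, and glucose-deprived (GD) cells were kept without glucose for 36 h. The 2 remaining groups were deprived for as long in the presence of empagliflozin at 100 µM or 200 µM. Empagliflozin is a glucose-lowering drug that inhibits the renal sodium-glucose cotransporter SGLT2, the product of Slc5a2. Values are transcripts per 1000000 (TPM), printed as mean ± SD (SD, n = 3 libraries), and log2 fold changes are differences of mean log2(TPM + 1), which understates the change of genes with low values. Adjusted p-values are from limma over all 12314 genes tested. The totals of the libraries were 946400.5 to 981389.8 TPM. TPM keep no record of the number of reads, so the depth is unknown. Genes are named by the symbols of the deposited table, which gives no coordinates.

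Glucose deprivation set the cells apart more than either dose of the drug did, and cells with 200 µM lay closest to control among the deprived groups. The correlation of log2 values across genes, which are not independent replicates, was 0.990 to 0.994 between libraries of 1 group. It was 0.873 to 0.887 between control and GD libraries, 0.875 to 0.896 between control and 100 µM and 0.909 to 0.922 between control and 200 µM. The root mean square log2 distance from the control mean was 1.19 to 1.38 in GD libraries, 1.17 to 1.30 at 100 µM and 0.98 to 1.06 at 200 µM. Ribosomal protein genes held 17.4% ± 0.30 of all TPM in control, 34.6% ± 1.70 in GD, 35.0% ± 1.66 at 100 µM and 32.4% ± 0.87 at 200 µM (SD, n = 3 each). The ferritin genes, whose products store iron, held 1.52% ± 0.03 in control and 4.84% ± 0.37 in GD. Between 12018 and 12074 genes reached 1 TPM in control libraries, 10551 to 10951 in GD, 10875 to 11078 at 100 µM and 11193 to 11322 at 200 µM. GD replicate 3 had the highest ferritin share (5.25%), the lowest median TPM of the tested genes (6.84) and the fewest genes at 1 TPM (10551) of the 12 libraries.

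**Figure D1:**
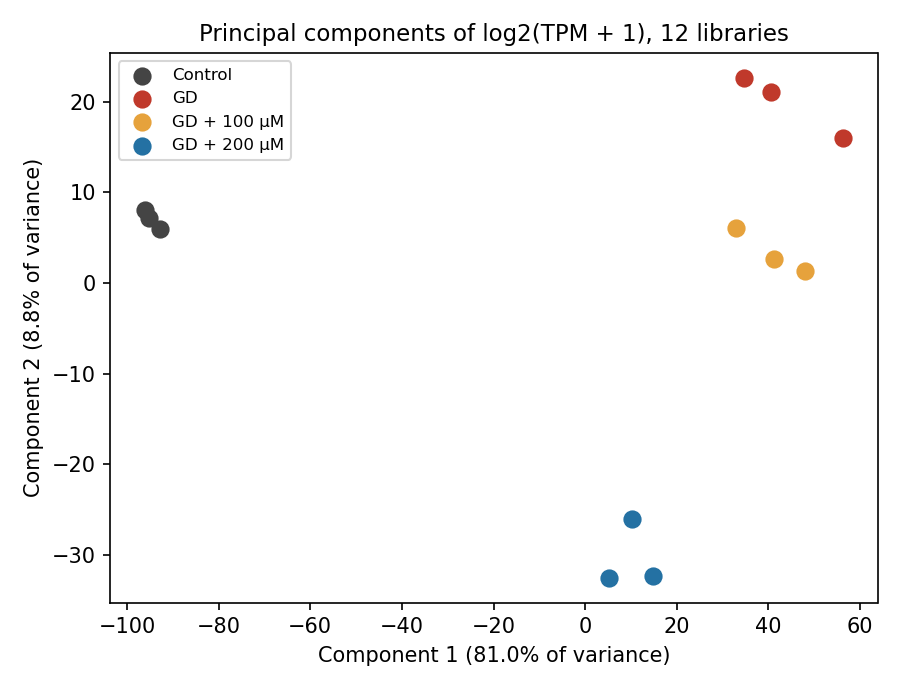
Principal components of log2(TPM + 1) of the 12 libraries, each point a library, with component 1 (81.0% of variance) on the horizontal axis and component 2 (8.8%) on the vertical axis, in arbitrary units. The GD libraries lie at 34.7 to 56.2 on component 1 and the libraries with 200 µM at 5.1 to 14.9, all far from the control libraries at -96 to -92.9.

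In every comparison with control, the larger share held by ribosomal protein and ferritin genes lowers the TPM of all others, so directions depend on scaling. The median log2 fold change of all tested genes was -0.65 for GD against control, -0.62 for 100 µM against control and -0.50 for 200 µM against control. It was 0.02 for 100 µM against GD, 0.14 for 200 µM against GD and 0.12 between the doses. After median-of-ratios scaling, an alternative chosen after the data were seen, each lay within 0.01 of 0. This scaling sets the typical gene to no change, so near-equal numbers of higher and lower genes after it are built in. Whether the typical gene was unchanged cannot be read from these values. Counts are of TPM as deposited unless this scaling is named, and changes against control that are smaller than these medians can turn with scaling.

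The first comparison asks what 36 h without glucose did to the cells. Thbs1, which encodes the matrix protein thrombospondin 1, fell from 1669.7 ± 56.1 to 5.55 ± 1.03 TPM (SD, n = 3; log2 fold change -8.01, SE 0.18, adjusted p = 1.92e-12). Ddit3, which encodes the stress transcription factor CHOP, rose from 61.9 ± 0.41 to 1269.9 ± 131 TPM (4.33, SE 0.11, adjusted p = 4.72e-12). Txnip, a gene induced by glucose whose product restrains glucose uptake, fell from 58.4 ± 3.21 to 0.16 ± 0.12 TPM (-5.69, SE 0.12). Genes of proliferation, muscle, matrix, contraction and sterol synthesis fell together, and many genes of the ribosome, of protein folding in the endoplasmic reticulum (ER) and of antioxidant defence rose. Of the 12314 genes, 10042 changed, 1722 upward and 8320 downward. After median-of-ratios scaling 4683 were higher and 4768 lower, which moves the lower share from 82.9% to 50.4%, and 1127 genes were called in opposite directions by the 2 scalings. The 4768 genes lower after that scaling were also lower in TPM as deposited, and the 1722 higher genes were higher under both. Against control that scaling raises changes by a near-equal amount, so the even split and this overlap are built in and are no separate support.

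Beside Ddit3, the strongest rises among the genes named by rule were in Slc17a1, a sodium-phosphate cotransporter gene (1.18 ± 0.38 to 162 ± 16.8 TPM; log2 fold change 6.24, SE 0.41), and Cxcl1, a chemokine gene (44.8 ± 10.25 to 1137 ± 287 TPM; 4.63, SE 0.26). Mcoln3, which encodes a lysosomal cation channel (4.51), Ankle1 (3.68) and the stress transcription factor gene Atf3 (3.97 ± 0.28 to 62.5 ± 2.20 TPM; 3.68) followed. Among the deepest falls were Ankrd1, a target of the growth regulator YAP (829 ± 66.2 to 9.74 ± 1.71 TPM; -6.28), and the chemokine gene Cxcl12 (539 ± 9.69 to 8.44 ± 0.49 TPM; -5.84). Ctgf, a matrix-associated growth factor gene (-5.84), and the connexin gene Gja5 (-5.71) fell as far.

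Proliferation genes were low throughout after deprivation. All 32 mitosis genes tested fell, with a median log2 fold change of -3.39 (camera adjusted p = 5.19e-09, adjusted p = 0.334 with an estimated correlation). Cdc20, an activator of mitotic exit, went from 54.9 ± 1.5 to 1.84 ± 0.21 TPM, and Anln (-4.27) and Kif20a (-4.23) fell as steeply. Of 39 DNA replication genes, 37 fell and 0 rose, with a median of -1.94 (adjusted p = 3.79e-06, adjusted p = 0.334 with an estimated correlation). Mcm5, part of the replicative helicase, fell from 61.5 ± 1.55 to 0.72 ± 0.14 TPM, and the thymidine kinase gene Tk1 (-4.74) and the ribonucleotide reductase gene Rrm2 (-3.94) fell too. After median-of-ratios scaling 32 of the mitosis genes and 34 of the replication genes were lower, and 2 replication genes were higher.

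Matrix, contractile and muscle genes fell as groups. All 28 genes of the list of contractile proteins and YAP-type, SRF-type and TGF-beta-type targets fell, with a median of -3.15 (adjusted p = 1.52e-07, adjusted p = 0.459 with an estimated correlation). In that list, smooth-muscle actin Acta2 went from 5946 ± 166 to 159 ± 5.91 TPM (-5.22, SE 0.08). Of 39 extracellular matrix genes 38 fell, with a median of -2.59 (adjusted p = 3.28e-06, adjusted p = 0.586 with an estimated correlation). Among them were the collagen crosslinking enzyme gene Lox (93.1 ± 4.25 to 1.06 ± 0.32 TPM), Timp1 (-2.71) and Col5a3 (-3.24). All 16 skeletal muscle genes tested, of 28 on the list, fell, with a median of -2.46 (adjusted p = 0.00106, adjusted p = 0.502 with an estimated correlation). They include the myogenic regulator Myog (20.5 ± 1.38 to 0.11 ± 0.07 TPM), Acta1 (-3.58) and Tnnc2 (-4.73). Only 7 of the 25 cardiac muscle genes on the list passed the expression filter. All 7 fell, with a median of -2.75 (adjusted p = 0.0122, adjusted p = 0.234 with an estimated correlation), such as Pln (-2.75), Tnnc1 (-3.88) and Hand2 (-2.12). After median-of-ratios scaling 1 contractile and 1 matrix gene were higher, and 27 and 35 lower.

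Lipid synthesis genes also fell. Of 24 cholesterol synthesis and uptake genes 23 fell and 1 rose, with a median of -1.78 (adjusted p = 0.000242, adjusted p = 0.586 with an estimated correlation). Acat2, whose product acts at the start of sterol synthesis, went from 180.3 ± 9.2 to 27.97 ± 3.03 TPM (-2.65). Of 13 fatty acid synthesis genes 12 fell, with a median of -2.05 (adjusted p = 0.0344, adjusted p = 0.665 with an estimated correlation). Elovl6 (-3.56), Acss2 (-2.99) and Fads2 (-3.19) were among them, while 2 were higher and 10 lower after median-of-ratios scaling. Of 24 pyruvate dehydrogenase and citric acid cycle genes 20 fell, with a median of -0.67, close to that of all genes (adjusted p = 0.0479, adjusted p = 0.665 with an estimated correlation), and median-of-ratios scaling gave 10 higher and 9 lower. Sdha (-1.16) and Mdh2 (-0.99, or -0.23 after that scaling) were among its members with the smallest p. That list lost its call without control replicate 1, control replicate 2, GD replicate 2 or GD replicate 3, with adjusted p up to 0.0672. It also lost it without ribosomal protein and ferritin genes and after median-of-ratios scaling, which turned its direction to up (adjusted p = 0.945).

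Ribosomal protein genes rose almost without exception. Of 75 tested, 72 rose and 1 fell, with a median of 0.97 (adjusted p = 6.98e-57, adjusted p = 0.216 with an estimated correlation). Rps3a went from 1270.4 ± 18.4 to 5034 ± 353 TPM, and Rps6 (1.74) and Rpl10 (1.35) rose too. ER chaperone and degradation genes, which help proteins fold in the secretory pathway, had 20 of 31 risen and 8 fallen, with a median of 0.89 (adjusted p = 2.62e-11, adjusted p = 0.459 with an estimated correlation). Dnajc3 went from 30.9 ± 3.18 to 154 ± 17.9 TPM, and Manf (1.81) and Fkbp2 (1.57) rose as well. Of 29 genes of antioxidant defence of the NRF2 type, 18 rose and 6 fell, with a median of 0.85 (adjusted p = 2.62e-11, adjusted p = 0.216 with an estimated correlation). The ferritin gene Fth1 rose from 6432 ± 137 to 23471 ± 2310 TPM, and the aldo-keto reductase gene Akr1b8 (2.52) and the superoxide dismutase gene Sod1 (0.91) rose too. After median-of-ratios scaling 74 ribosomal, 26 ER and 26 antioxidant genes were higher and 0, 4 and 3 lower.

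Several stress lists held members that moved both ways. Median-of-ratios scaling raises changes against control in general, so with it their balance shifted upward, as the medians of all other lists did. Of 39 genes of the integrated stress response, the program by which cells answer amino acid shortage and other stress, 15 rose and 15 fell, with 29 higher and 6 lower after median-of-ratios scaling (median 0.04, adjusted p = 2.4e-05, adjusted p = 0.586 with an estimated correlation). Beside Ddit3, the phosphatase subunit gene Ppp1r15a (2.83) and the amino acid transporter gene Slc3a2 (298 ± 13.9 to 1496 ± 129 TPM) led it. Of 37 lysosome genes 18 rose and 11 fell, or 30 and 4 after that scaling (median 0.10, adjusted p = 1.52e-07, adjusted p = 0.546 with an estimated correlation). Mcoln1 (1.93), Lamp1 (0.92) and the enzyme gene Gusb (-1.83) had the smallest p. Of 41 autophagy genes 15 rose and 21 fell, or 24 and 11 after that scaling. Their median (-0.23) and mean (-0.15) were negative while camera, which compares the list with all other genes, placed it upward (adjusted p = 0.00309, adjusted p = 0.665 with an estimated correlation). The cargo receptor gene Sqstm1 rose from 641 ± 23.3 to 2028 ± 104 TPM, Gabarapl1 from 48.2 ± 2.61 to 171 ± 8.04 TPM, and Gabarap by 0.87. Of 19 cytosolic heat shock genes 9 rose and 5 fell, or 15 and 2 after that scaling, with a median of 0.21 and a mean of -0.08 (upward, adjusted p = 0.000215, adjusted p = 0.357 with an estimated correlation). Hspa8 rose by 0.95, while Dnajb4 (-3.09) and Cryab (-2.09) fell. Of 25 inflammation genes 12 rose and 6 fell, or 11 and 6 adjusted over the list alone, and 18 and 4 after that scaling (median 0.41, adjusted p = 3.11e-05, adjusted p = 0.502 with an estimated correlation), with Cxcl1 up and Cxcl12 and Il1rl1 (-3.56) down. Fry did not call the integrated stress response (0.0881), heat shock (0.399), autophagy (0.384) and inflammation lists (0.0549), and gave the last 2 a downward direction.

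The remaining lists did not pass by camera, which compares a list with all other genes, and the adjusted p-values given here are of camera. Fry called all of them downward, with adjusted p from 1.5e-09 for glucose-sensor genes to 0.00508 for ribosome biogenesis. It was run on TPM as deposited, in which the median of all genes was itself -0.65. Of 62 nuclear-encoded respiratory chain genes, 51 fell and 3 rose, with a median of -0.50 (adjusted p = 0.069), with Cyc1 at -1.44. After median-of-ratios scaling 34 were higher and 7 lower (adjusted p = 0.00872, upward). Of 37 ribosome biogenesis genes 19 fell and 6 rose (0.116), against 5 and 25 after that scaling (0.00212, upward). Of 21 glycolysis genes 16 fell and 2 rose (adjusted p = 0.116), and the lactate dehydrogenase gene Ldha fell from 854 ± 22.7 to 111 ± 6.94 TPM. Of 6 glucose-sensor genes 5 fell (0.116), and of 9 hexosamine genes 4 fell and 2 rose (0.576), with the O-GlcNAc hydrolase gene Mgea5 at -3.02. Of 23 fatty acid oxidation genes 18 fell and 4 rose (0.655), with Acadvl at -3.07. Of 24 p53 targets 14 fell and 5 rose (0.233), the growth arrest gene Gadd45a among the latter at 3.02. Of 30 apoptosis and necroptosis genes 23 fell and 3 rose (0.61), with Birc3 at 2.59. Of 18 hypoxia genes 9 fell and 5 rose (0.173), and of 22 interferon-stimulated genes 13 fell and 4 rose (0.526). Of 16 FOXO and atrophy genes 13 fell and 2 rose (0.576) and of 16 immediate-early genes 11 fell and 3 rose (0.727). After median-of-ratios scaling the p53, hexosamine, apoptosis, hypoxia and interferon lists had more genes higher than lower. Markers of other cell types were few among tested genes: all 6 fibroblast genes (0.0706), 2 of 3 endothelial genes (0.526) and all 3 leukocyte genes (0.42) fell. With that scaling 5 fibroblast genes were lower and their list passed downward (0.0267). Adjusted over the list alone, the counts of this comparison were the same, except for inflammation and for FOXO genes, of which 14 fell.

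Sodium-handling genes, a group of interest for an inhibitor of sodium-glucose cotransport, fell in 18 of 20 cases and rose in 2. The adjusted p was 0.116 by camera and 8.9e-07 by fry, the latter downward. After median-of-ratios scaling 13 were lower and 2 higher (camera adjusted p = 0.0473). Slc5a2 fell from 7.26 ± 0.57 to 1.02 ± 0.22 TPM (-2.04, adjusted p = 7.47e-08), and the sodium-glucose cotransporter gene Slc5a1 was at 0.01 ± 0.02 TPM in control, listed at 0 in GD and too low to be tested. Slc9a3r1, which encodes a scaffold protein, fell by 1.83. The autophagy gene Becn1 fell by 0.36 as deposited (adjusted p = 0.00163) and rose by 0.39 after that scaling, and Map1lc3b rose by 0.32. The glucose transporter gene Slc2a1 was at 12.8 ± 0.25 TPM in control and 14.0 ± 0.83 TPM in GD (adjusted p = 0.543), and at 0.83 with adjusted p = 0.00184 after that scaling.

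No label states whether the 3 libraries of a group are separate cultures, so p-values may measure only technical spread. No label gives the serum of the deprived groups, so glucose is not shown to be the sole difference from control. No label names the solvent of the drug or a solvent given to the GD cells, so the comparisons of drug with GD cannot tell the drug from its solvent.

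**Figure D2:**
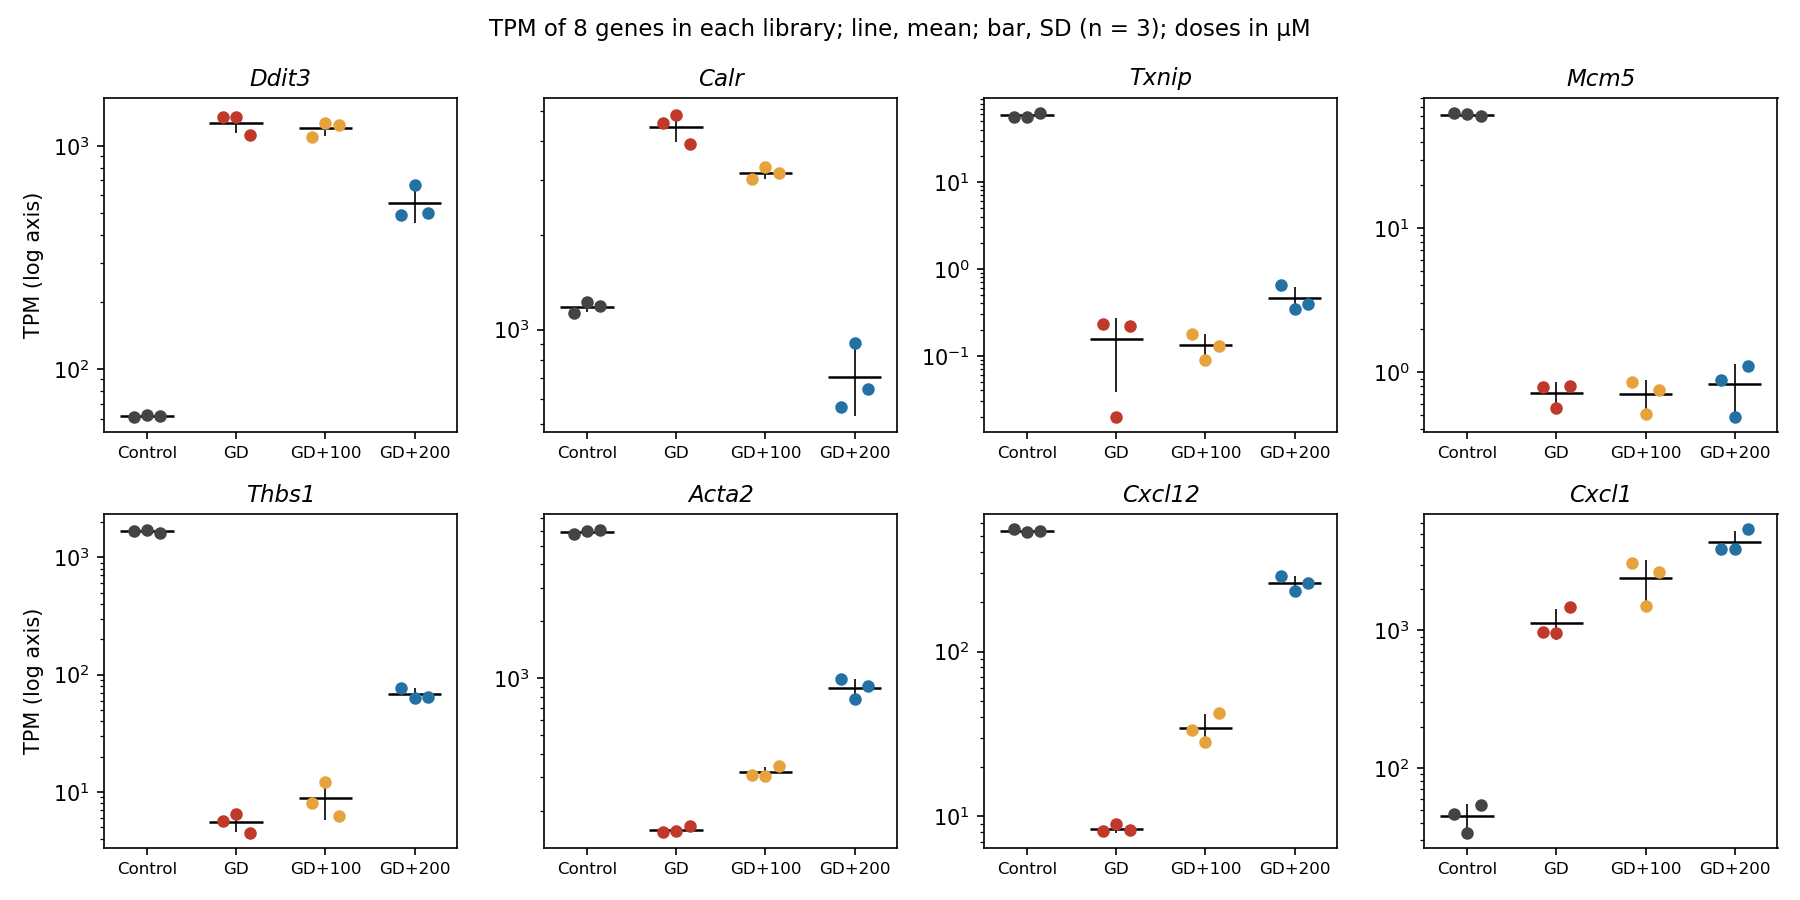
TPM of 8 genes in each library on a log axis, by group; points are libraries, lines means and bars SD (n = 3). Calr falls to 706 ± 179 TPM at 200 µM, below the 1183 ± 48.5 TPM of control, Mcm5 stays under 1 TPM in mean in all 3 deprived groups, and Cxcl1 is highest at 200 µM with 4414 ± 860.5 TPM.

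The next comparison asks what 100 µM empagliflozin changed in deprived cells. Inflammation genes rose: Nos2, which encodes the inducible nitric oxide synthase, went from 0.76 ± 0.14 to 9.31 ± 4.17 TPM (SD, n = 3; log2 fold change 2.46, SE 0.27, adjusted p = 0.000181), and Cxcl12 from 8.44 ± 0.49 to 34.6 ± 7.07 TPM (1.90, SE 0.12, adjusted p = 8.28e-06). Of 62 respiratory chain genes 33 rose by small amounts, while 7 of 19 heat shock, 13 of 37 lysosome and 10 of 29 antioxidant genes fell. These lists passed by camera but not with an estimated correlation (adjusted p = 0.284, 0.284, 0.929 and 0.304). Of the mitosis, DNA replication, ribosomal protein and skeletal muscle genes 0 were called by limma, also adjusted over the list alone; 1, 7, 9 and 0 of them had an unadjusted p under 0.05, and fry gave adjusted p = 0.668, 0.668, 0.668 and 0.846. Median-of-ratios scaling left 0 calls in these lists except DNA replication, with 2 higher and 5 lower. Of their members followed through the alternatives, Rps9 and Mcm7 passed with quantile normalization (adjusted p = 0.0401 and 0.0279), array weights (0.00667 and 0.00313) and without GD replicate 3 (0.0197 and 0.0147). Rps9 also passed with a filter of 5 TPM (0.0472) and a pseudocount of 0.1 (0.047), Mcm7 with replicate number as an added term (0.0446) and without ribosomal protein and ferritin genes (0.0369), and Cdh15 without 100 µM replicate 2 (0.0146). Of 12314 genes, 1597 changed, 925 upward and 672 downward, and after median-of-ratios scaling 997 and 1276. At 2-fold or more, 53 were higher and 22 lower.

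Other strong rises were in Pla2g2a, a secreted phospholipase gene (0.95 ± 0.25 to 11.2 ± 8.19 TPM; 2.44), and in the cytokine and acute-phase genes Cxcl2 (0.87 ± 0.05 to 8.79 ± 3.37 TPM; 2.32), Csf2 (2.14) and Lcn2 (1.90), of which Csf2 and Lcn2 were listed at 0 in control. The largest falls by the naming rule were in Mlana (16.9 ± 3.12 to 5.38 ± 4.09 TPM; -1.66, adjusted p = 0.0123, or 0.0521 without 100 µM replicate 3), Armc8 (122 ± 26.1 to 39.6 ± 3.78 TPM; -1.58), Ampd3 (-1.40), the nuclear receptor gene Nr4a1 (-1.35), Serpinb1a (-1.34) and the growth factor gene Fgf7 (-1.25).

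Of 25 inflammation genes 18 rose and 0 fell (19 adjusted over the list alone), with a median of 0.77 (adjusted p = 1.43e-11, adjusted p = 0.304 with an estimated correlation). Ccl7 went from 154 ± 24.3 to 439.5 ± 80.0 TPM. Of 62 respiratory chain genes 33 rose and 0 fell (41 and 1 adjusted over the list alone; 19 and 0 after median-of-ratios scaling), with a median of 0.23 (adjusted p = 2.09e-14, adjusted p = 0.284 with an estimated correlation). Ndufs5 went from 232 ± 6.36 to 304 ± 7.80 TPM, and Atp5o (0.35) and Ndufb8 (0.33) rose alike. Of 24 cholesterol genes 7 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.26 (adjusted p = 2e-04, adjusted p = 0.929 with an estimated correlation). Sqle (0.58) and Pmvk (0.50) rose. Of 28 contractile genes 4 rose and 0 fell (6 and 1 adjusted over the list alone), with a median of 0.21 (adjusted p = 0.0126, adjusted p = 0.929 with an estimated correlation). Acta2 was among them (159 ± 5.91 to 319.5 ± 20.1 TPM), with Ctgf (0.88) and the YAP target Amotl2 (0.84; 5.80 ± 0.33 to 11.1 ± 0.24 TPM). The list missed the threshold without 100 µM replicate 2 (adjusted p = 0.13). Of 22 interferon-stimulated genes 3 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.0494, adjusted p = 0.929 with an estimated correlation). Psmb9 was at 0.92, Irf7 at 0.62 and Isg15 at 0.92 (adjusted p = 0.0429, or up to 0.165 without GD replicate 1 or 2 or 100 µM replicate 1 or 3). Isg15 also missed the threshold with no filter, limma without trend, the 2 groups alone, quantile normalization or median-of-ratios scaling (0.0578 to 0.122). Median-of-ratios scaling gave 17 higher and 0 lower for inflammation, 9 and 1 for cholesterol, 6 and 1 for contractile and 3 and 1 for interferon genes. The interferon list missed the threshold after that scaling (0.0515) and without GD replicate 1, GD replicate 2 or 100 µM replicate 1, with adjusted p up to 0.215.

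Of 19 heat shock genes 7 fell and 0 rose (13 fell adjusted over the list alone), with a median of -0.35 (adjusted p = 2.59e-08, adjusted p = 0.284 with an estimated correlation). The chaperone gene Hsp90ab1 went from 1554 ± 53.4 to 1072 ± 20.9 TPM, and Bag3 (-0.71) and Dnajb1 (-0.43) fell. Of 37 lysosome genes 13 fell and 1 rose (15 and 2 adjusted over the list alone), with a median of -0.17 (adjusted p = 1.6e-07, adjusted p = 0.929 with an estimated correlation). They include Lamp1 (-0.38) and the enzyme gene Hexa (-0.48). Of 29 antioxidant genes 10 fell and 3 rose (16 and 3 adjusted over the list alone), with a median of -0.31 (adjusted p = 2e-07, adjusted p = 0.304 with an estimated correlation). Osgin1 (-1.22) and the pentose phosphate enzyme gene Tkt (-0.74) fell and the peroxidase gene Gpx1 rose (155 ± 3.35 to 215 ± 15.9 TPM). Smaller shifts were called in 3 further lists. Of 21 glycolysis genes 4 fell and 0 rose (4 and 1 adjusted over the list alone; adjusted p = 0.00448, adjusted p = 0.929 with an estimated correlation). However, 2 were lower and 1 higher after median-of-ratios scaling, and the list missed the threshold without GD replicate 3 (0.0526). Gpi was at -0.28, Aldoa at -0.23 and Gapdh at -0.19, and after that scaling Aldoa (adjusted p = 0.0891) and Gapdh (0.127) did not pass. Aldoa also missed the threshold without GD replicate 2 or 100 µM replicate 1 or 2, and Gpi without 100 µM replicate 1 (adjusted p up to 0.0697). With a fit of the 2 groups alone none of the 3 passed (Gpi 0.0673, Aldoa 0.0713, Gapdh 0.0793), nor did Aldoa (0.0695) and Gapdh (0.0807) without trend or Aldoa with quantile normalization (0.0744). Of 41 autophagy genes 5 fell, with the same number adjusted over the list alone (adjusted p = 0.0154, adjusted p = 0.929 with an estimated correlation). These include Gabarapl1 (171 ± 8.04 to 99.1 ± 0.51 TPM), Pink1 (-0.48) and Uvrag (-0.37), the last of which missed the threshold without any 1 of the GD replicates 1 and 2 or the 100 µM libraries (adjusted p up to 0.122), without trend (0.0508), with no filter (0.0742) and with the 2 groups alone (0.107). Of 31 ER chaperone genes 5 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.0154, adjusted p = 0.929 with an estimated correlation). Dnajc3 was at -0.53, P4hb at -0.30 and Sec61b at 0.29. Without GD replicate 2 or 100 µM replicate 2 the autophagy list (adjusted p up to 0.071) and the ER list (up to 0.0658) missed the threshold. With median-of-ratios scaling 11 heat shock genes fell and 0 rose, 15 and 1 of the lysosome, 16 and 2 of antioxidant defence, 8 and 1 of autophagy and 9 and 1 of the ER list. Of the 11 lists called by camera, fry called 4 and not cholesterol (0.159), contractile (0.189), interferon (0.449), lysosome (0.159), glycolysis (0.159), autophagy (0.589) or ER genes (0.668).

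Among the genes fixed in advance, Ddit3 (-0.08, adjusted p = 0.685), Txnip (-0.02, 0.923), Sqstm1 (-0.19, 0.111), Map1lc3b (-0.09, 0.359), Becn1 (-0.01, 0.963), Slc2a1 (0.02, 0.963) and Slc5a2 (-0.31, 0.247) did not pass, although Slc5a2 did with array weights (-0.45, 0.0293). Single libraries weighed on this comparison: 1006 genes were called without GD replicate 1, 2476 without GD replicate 3 and 1005 without 100 µM replicate 3.

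The third comparison asks the same of 200 µM. Calr, which encodes the ER chaperone calreticulin, fell from 4443 ± 472 in GD to 706 ± 179 TPM (SD, n = 3; log2 fold change -2.68, SE 0.13, adjusted p = 3.12e-08), below the control mean of 1183 ± 48.5 TPM. Ddit3 fell from 1269.9 ± 131 to 553 ± 99.9 TPM (-1.21, adjusted p = 2.88e-06). Inflammation, interferon, contractile, matrix and cholesterol genes rose: Pla2g2a went from 0.95 ± 0.25 to 186 ± 10.55 TPM (6.58, SE 0.35, adjusted p = 5.38e-08) and Cxcl12 from 8.44 ± 0.49 to 259.9 ± 26.8 TPM (4.78, SE 0.12, adjusted p = 7.82e-11). Of 12314 genes 5350 changed, 3944 upward and 1406 downward, against 2792 and 2952 after median-of-ratios scaling, which moves the lower share from 26.3% to 51.4%. Of these, 2790 were higher and 1406 lower under both scalings, and 590 were higher and 138 lower by 2-fold or more. Against GD that scaling lowers changes by a near-equal amount, so the even split and most of the overlap are built in.

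H19, a long non-coding RNA gene, rose from 93.6 ± 11.7 to 1165 ± 215 TPM (3.61), against 4419.6 ± 161 TPM in control. Nos2 (4.22), Tgm2, a transglutaminase gene (1.93 ± 0.41 to 30.7 ± 7.27 TPM; 3.42), and Thbs1 (5.55 ± 1.03 to 68.2 ± 7.99 TPM; 3.41) were the other largest rises by the naming rule. The largest falls were in Ppef1 (12.1 ± 1.45 to 0.75 ± 0.33 TPM; -2.91), Plac1 (-2.82), Mlana (-2.72), the ER chaperone cofactor gene Sdf2l1 (532 ± 25.6 to 84.1 ± 25.9 TPM; -2.69) and Avil (-2.65).

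Of 31 ER chaperone genes 24 fell and 0 rose (26 fell adjusted over the list alone), with a median of -0.94 (adjusted p = 1.58e-23, adjusted p = 0.444 with an estimated correlation). Dnajc3 went from 154 ± 17.9 to 29.0 ± 4.78 TPM and Fkbp2 from 450.03 ± 11.04 to 124 ± 16.5 TPM. Of 29 antioxidant genes 17 fell and 5 rose (17 and 7 adjusted over the list alone), with a median of -0.33 (adjusted p = 6.37e-05, adjusted p = 0.478 with an estimated correlation). Txnrd1 fell by 0.69, but the mitochondrial superoxide dismutase gene Sod2 rose from 104 ± 17.9 to 554 ± 106 TPM and Gpx1 by 0.85. Of 37 lysosome genes 17 fell and 10 rose (19 and 10 adjusted over the list alone), with a median of -0.21 (adjusted p = 6.68e-05, adjusted p = 0.685 with an estimated correlation). Lamp1 (-0.59) and the proton pump gene Atp6v1h (149 ± 20.9 to 73.1 ± 4.24 TPM) fell and the protease gene Ctsf (0.71) rose. Of 19 heat shock genes 9 fell and 0 rose, with the same count adjusted over the list alone and a median of -0.16 (adjusted p = 0.000394, adjusted p = 0.475 with an estimated correlation). Hspa4l (-1.08), Bag3 (-0.59) and Chordc1 (-0.45) had the smallest p. Of 41 autophagy genes 12 fell and 8 rose, with the same counts adjusted over the list alone. The median was 0.10, the mean -0.05 and the list test downward (adjusted p = 0.0122, adjusted p = 0.881 with an estimated correlation), and median-of-ratios scaling gave 18 lower and 5 higher with a median of -0.08. Tecpr1 (-1.28), Gabarapl1 (-0.93), Sqstm1 (-0.60) and Map1lc3b (-0.43) fell. Of 75 ribosomal protein genes 20 fell and 4 rose (17 and 4 adjusted over the list alone), with a median of -0.09 (adjusted p = 3.83e-07, adjusted p = 0.667 with an estimated correlation), and 25 were lower and none higher after median-of-ratios scaling. The same scaling gave 28 lower and 0 higher for ER chaperones, 19 and 4 for antioxidant, 25 and 7 for lysosome and 11 and 0 for heat shock genes. Rpl30 (-0.53), Rps3a (-0.41) and Rpl10 (-0.41) fell. Fry did not call the lysosome (adjusted p = 0.102), autophagy (0.39) and ribosomal protein lists (0.123).

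Of 25 inflammation genes 23 rose and 0 fell, also adjusted over the list alone, with a median of 1.56 (adjusted p = 5.14e-11, adjusted p = 0.444 with an estimated correlation). Beside Cxcl12 and Nos2, Socs3, a feedback inhibitor of cytokine signalling, went from 2.74 ± 0.92 to 23.9 ± 4.10 TPM. Of 22 interferon-stimulated genes 17 rose and 1 fell, also adjusted over the list alone, with a median of 1.01 (adjusted p = 0.000635, adjusted p = 0.667 with an estimated correlation). The transcription factor genes Irf7 (9.99 ± 0.71 to 41.9 ± 8.41 TPM) and Irf9 (1.08) rose, as did Ifi44 (1.35). Of 28 contractile genes 24 rose and 0 fell (24 and 2 adjusted over the list alone), with a median of 1.18 (adjusted p = 2.58e-10, adjusted p = 0.475 with an estimated correlation). Acta2 rose to 892 ± 104 TPM and Amotl2 by 1.97. Of 39 matrix genes 31 rose and 3 fell (32 and 3 adjusted over the list alone), with a median of 0.87 (adjusted p = 3.24e-06, adjusted p = 0.667 with an estimated correlation). Lox went from 1.06 ± 0.32 to 14.0 ± 1.41 TPM, and Col4a1 (1.55) and Timp1 (1.27) rose. Of 6 fibroblast markers 5 rose, also adjusted over the list alone (median 0.82, adjusted p = 0.0172, adjusted p = 0.667 with an estimated correlation). S100a4 went from 811 ± 15.6 to 2687 ± 439 TPM, with Lum at 1.04 and Ddr2 at 0.87. Of 24 cholesterol genes 20 rose and 1 fell, also adjusted over the list alone, with a median of 0.66 (adjusted p = 4.82e-05, adjusted p = 0.667 with an estimated correlation). Acat2 (1.12) and Pmvk (0.85) rose, whereas Insig1, a feedback inhibitor of sterol synthesis, fell by 0.83. Of 62 respiratory chain genes 50 rose and 1 fell (52 and 1 adjusted over the list alone), with a median of 0.37 (adjusted p = 3.45e-10, adjusted p = 0.444 with an estimated correlation) and 22 higher and 1 lower after median-of-ratios scaling. Ndufa3 (54.8 ± 7.58 to 107 ± 6.18 TPM), Cox6c (0.67) and Cyc1 (0.62) rose. That scaling gave 22 higher and 0 lower for inflammation, 16 and 2 for interferon, 24 and 2 for contractile, 31 and 4 for matrix, 5 and 0 for fibroblast and 17 and 1 for cholesterol genes.

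Lists of the cell cycle and muscle did not pass by camera: of 32 mitosis genes 3 rose (1 adjusted over the list alone; adjusted p = 0.456), of 39 replication genes 9 rose and 5 fell (9 and 4 adjusted over the list alone; 0.37), of 16 skeletal genes 6 rose (0.421) and of 7 cardiac genes 4 rose (0.314), the muscle lists with the same counts adjusted over the list alone. Cdk1 (0.94), Rrm2 (0.97), Klhl41 (1.79) and the connexin gene Gja1 (2.28) were their members with the smallest p. The integrated stress response list, with 9 up and 10 down (10 and 11 adjusted over the list alone; 0.107), and the glycolysis list, with 9 up and 5 down (the same adjusted over the list alone; 0.764), did not pass either. Median-of-ratios scaling gave 1 higher and 2 lower for mitosis, 7 and 11 for replication, 5 and 0 for skeletal muscle and 1 and 0 for cardiac muscle. It gave 7 and 15 for the integrated stress response and 5 and 8 for glycolysis. By fry the skeletal (adjusted p = 0.0297), cardiac (4.63e-05) and glycolysis lists (0.0102) passed upward, and those of mitosis, replication and the integrated stress response did not (0.335, 0.208 and 0.974). Ddit4 rose by 1.54 and Ldha by 1.00. The markers of leukocytes, of which 2 of 3 rose, did not pass as a list by camera (0.37) but did by fry (0.00155). Txnip rose from 0.16 ± 0.12 to 0.46 ± 0.16 TPM (0.34, adjusted p = 0.0301), a call lost without GD replicate 2 (0.11) or 200 µM replicate 1 (0.134), with no filter (0.0586) and with quantile normalization (0.18, 0.305). Slc5a2 (0.18, adjusted p = 0.393), Becn1 (-0.14, 0.214) and Slc2a1 (0.20, 0.412) did not pass, although Becn1 did after median-of-ratios scaling (-0.33, 0.000317) and without GD replicate 3 (-0.22, 0.0434). It also passed with quantile normalization (0.00994), array weights (0.0176) and without ribosomal protein and ferritin genes (0.0302).

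**Figure D3:**
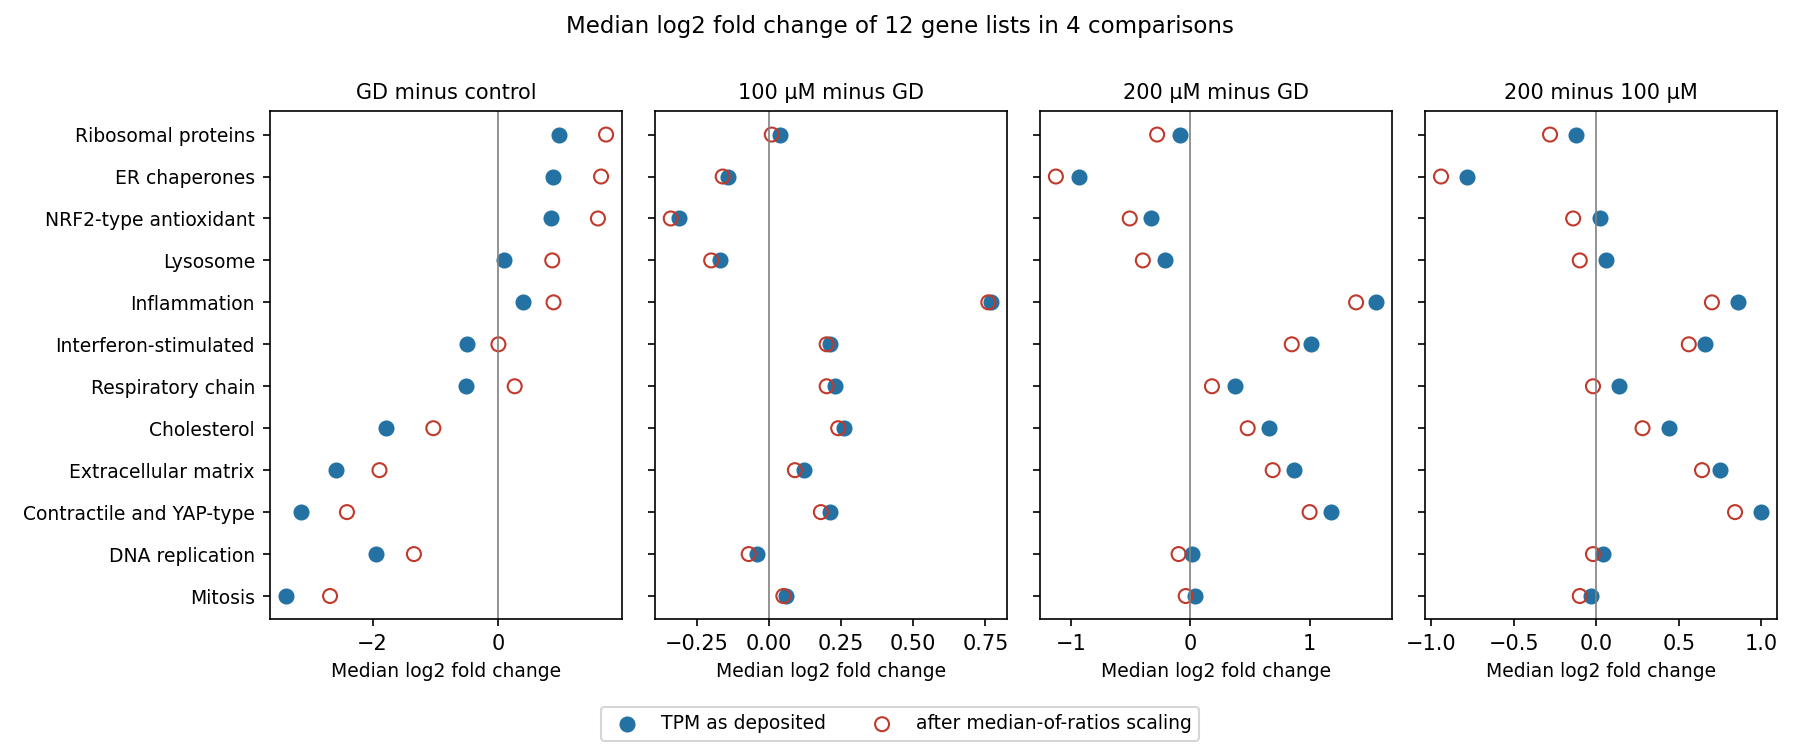
Median log2 fold change (horizontal axis) of 12 gene lists in 4 comparisons; filled points are TPM as deposited and open points median-of-ratios scaling. ER chaperones fall by 0.94 at 200 µM against GD and inflammation genes lie at 1.56, whereas the respiratory chain median for GD against control changes from -0.50 to 0.27 with scaling.

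The doses were then compared directly, without GD libraries in the contrast. ER chaperone genes were lower and inflammation, contractile and matrix genes higher at 200 µM. Calr was at 3169.5 ± 132 TPM with 100 µM and 706 ± 179 TPM with 200 µM (SD, n = 3; log2 fold change -2.19, adjusted p = 3.49e-07), and Pla2g2a at 11.2 ± 8.19 and 186 ± 10.55 TPM (4.15, adjusted p = 3.65e-06). Angptl4, a lipase inhibitor gene, rose from 6.75 ± 2.59 to 74.8 ± 13.95 TPM (3.34, adjusted p = 1.11e-06), and Cyr61, a YAP target, from 5.09 ± 1.52 to 49.2 ± 2.94 TPM (3.07, adjusted p = 1.98e-07). Of 12314 genes 4159 differed, 3167 higher and 992 lower at 200 µM, against 2296 and 2281 after median-of-ratios scaling, which moves the lower share from 23.9% to 49.8%. Under both scalings 2294 were higher and 987 lower. That scaling lowers changes in this contrast too, so the even split and most of this overlap are built in. Cxcl12 (2.89), Igfbp5 (2.86) and Thbs1 (2.86) were the other largest rises, and Sdf2l1 (-2.65), Fez1 (-2.62), Plac1 (-2.46), the ER gene Creld2 (160 ± 16.2 to 33.4 ± 11.7 TPM; -2.27) and Ppef1 (-2.10) fell most.

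Of 31 ER chaperone genes 26 fell and 0 rose (27 fell adjusted over the list alone; median -0.78, adjusted p = 7.27e-28, adjusted p = 0.543 with an estimated correlation), with Fkbp2 at -1.65 and Manf at -1.58. Of 28 contractile genes 24 rose and 0 fell (25 rose adjusted over the list alone; median 1.00, adjusted p = 7.39e-12, adjusted p = 0.543 with an estimated correlation). Of 39 matrix genes 30 rose and 1 fell (31 and 1 adjusted over the list alone; median 0.75, adjusted p = 6.96e-07, adjusted p = 0.714 with an estimated correlation). Of 25 inflammation genes 21 rose and 0 fell, also adjusted over the list alone (median 0.86, adjusted p = 1.35e-06, adjusted p = 0.553 with an estimated correlation), with Tnf from 0.80 ± 0.46 to 4.97 ± 1.23 TPM and Socs3 at 2.00. Of 22 interferon-stimulated genes 15 rose and 1 fell (17 and 1 adjusted over the list alone; median 0.66, adjusted p = 0.00264, adjusted p = 0.714 with an estimated correlation), such as Ifit1 (1.93). All 6 fibroblast markers rose, also adjusted over the list alone (median 0.82, adjusted p = 0.00243, adjusted p = 0.553 with an estimated correlation), with S100a4 at 1.45, Gsn at 1.08 and Thy1 at 0.90. Of 16 immediate-early genes 10 rose and 1 fell (10 and 2 adjusted over the list alone; median 0.50, adjusted p = 0.0131, adjusted p = 0.543 with an estimated correlation), Egr1 from 1.67 ± 0.36 to 15.7 ± 3.68 TPM. Median-of-ratios scaling gave 27 lower and 0 higher for ER chaperones, and 24 higher and 0 lower for contractile, 30 and 2 for matrix, 16 and 0 for inflammation, 14 and 2 for interferon, 5 and 0 for fibroblast and 9 and 2 for immediate-early genes.

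Metabolic lists moved less. Of 23 fatty acid oxidation and PPAR-type genes 14 rose and 0 fell (15 rose adjusted over the list alone; 9 and 5 after median-of-ratios scaling), with a median of 0.29 (adjusted p = 0.0158, adjusted p = 0.834 with an estimated correlation). Cpt1a, the carnitine transferase that admits fatty acids to mitochondria (6.36 ± 0.89 to 19.3 ± 2.39 TPM; 1.46), and the thiolase gene Acaa2 (1.43) rose with Angptl4. Of 24 cholesterol genes 15 rose and 1 fell (17 and 1 adjusted over the list alone; median 0.44, adjusted p = 0.0116, adjusted p = 0.834 with an estimated correlation), with Dhcr7 at 0.87, but the list missed the threshold without 100 µM replicate 3 (0.0641). Of 62 respiratory chain genes 28 rose and 6 fell (31 and 6 adjusted over the list alone; median 0.14, adjusted p = 0.0272, adjusted p = 0.834 with an estimated correlation), but 8 were higher and 7 lower after median-of-ratios scaling (0.996). That call was also lost without 100 µM replicate 3 or 200 µM replicate 1 (adjusted p up to 0.11); Uqcrh rose by 1.18 and Uqcrq fell by 0.42. Of 75 ribosomal protein genes 25 fell and 2 rose (27 and 2 adjusted over the list alone; median -0.12, adjusted p = 7.39e-12, adjusted p = 0.714 with an estimated correlation). Of 37 ribosome biogenesis genes 7 fell and 2 rose (median -0.04, adjusted p = 0.00819, adjusted p = 0.834 with an estimated correlation). Of 39 integrated stress response genes 12 fell and 6 rose (median -0.01, adjusted p = 0.00914, adjusted p = 0.848 with an estimated correlation). Of 9 hexosamine genes 4 fell and 1 rose (median -0.23, adjusted p = 0.0103, adjusted p = 0.714 with an estimated correlation). These 3 lists had the same counts adjusted over the list alone. With median-of-ratios scaling 26 ribosomal protein genes fell and 0 rose, 17 and 1 of ribosome biogenesis (median -0.20), 16 and 3 of the integrated stress response and 7 and 1 of the hexosamine pathway, while 10 cholesterol genes rose and 3 fell. Fry did not call the ribosomal protein (0.0506), ribosome biogenesis (0.618), integrated stress response (0.662) and hexosamine lists (0.128). Ddit3 fell by 1.13, Sqstm1 by 0.41 and Map1lc3b by 0.34, and Txnip was higher by 0.36 (adjusted p = 0.0271) and Slc5a2 by 0.49 (adjusted p = 0.0337). Both calls were lost without 100 µM replicates 2 or 3 or 200 µM replicate 1, that of Slc5a2 also without 100 µM replicate 1, with adjusted p up to 0.143. Quantile normalization (Txnip 0.126, Slc5a2 0.0955) and no filter (0.0547 and 0.0844) ended both calls too, and a fit of the 2 groups alone that of Slc5a2 (0.0701). Becn1 (-0.13, adjusted p = 0.27) and Slc2a1 (0.18, 0.488) did not pass, although Becn1 did after median-of-ratios scaling (-0.29, 0.0012) and quantile normalization (-0.20, 0.0158).

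The last question is how far the drug moved deprived cells back toward control. At 200 µM, 4303 of the 10042 genes changed by deprivation moved in the opposite direction, 3515 of them from low to higher and 788 from high to lower, and 412 moved further. At 100 µM 1014 moved in the opposite direction, 703 from low to higher and 311 from high to lower, and 332 moved further. The split by direction depends on the scaling: median-of-ratios scaling gave 2037 from low to higher and 2270 from high to lower at 200 µM, and 508 and 818 at 100 µM. The genes named for reversal rose at both doses after the deepest falls: Cxcl12, Ctgf, H19, Acta2, the immediate-early gene Egr1 and the cyclin gene Ccnd1. H19 went from 4419.6 ± 161 TPM in control to 93.6 ± 11.7 in GD, 345 ± 65.9 at 100 µM and 1165 ± 215 at 200 µM. Ccnd1 went from 316 ± 21.8 to 9.41 ± 2.30, 14.3 ± 3.42 and 40.3 ± 5.33 TPM, and Ctgf from 588 ± 3.67 to 9.42 ± 2.02, 18.9 ± 7.55 and 108 ± 24.0 TPM. All 6 stayed below control at 200 µM. At 100 µM the calls of Ctgf (0.88), Egr1 (0.57) and Ccnd1 (0.56) were lost without GD replicate 1, 100 µM replicate 2 or 100 µM replicate 3, and those of Ctgf and Ccnd1 also without GD replicate 3, with adjusted p up to 0.157. The calls of all 3 were also lost with no filter (Ctgf 0.0796, Egr1 0.0872, Ccnd1 0.13) and with a fit of the 2 groups alone (0.0873, 0.0571 and 0.16). Replicate number as an added term ended that of Egr1 (0.0534), and rescaling to a common total (0.0565) and limma without trend (0.0675) that of Ccnd1. The median share of the deprivation change that was undone was 25% ± 3.2 (SD, n = 3 libraries) at 200 µM and 4.4% ± 5.6 at 100 µM, or 24.8% and 4.3% from group means. Against control, 9937 genes still differed at 100 µM (1738 higher, 8199 lower) and 9379 at 200 µM (1645 higher, 7734 lower). After median-of-ratios scaling these were 4716 higher and 4712 lower, and 4328 higher and 4411 lower.

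Because both contrasts use the same GD libraries, chance error in these looks like reversal, and 3 libraries cannot be halved, so part of the reversal may come from the shared libraries. In 100 simulations without a drug effect the mean share undone was 1.75% at 200 µM (range -12.4 to 12.7) and 0.72% at 100 µM (-9.9 to 12), so the share at 100 µM lay within that range and the share at 200 µM above it. The simulated means of opposite calls were 0.03 at 200 µM and 0.07 at 100 µM. Without a drug effect only 0.13 genes in mean were called against GD at either dose. These counts are thus near 0 by design and do not show how far the shared libraries raise 4303 and 1014. Lists drawn independently would share 2861 at 200 µM and 719 at 100 µM. Lists drawn independently would give 1502 and 583 genes moved further, more than the 412 and 332 seen. The correlation across genes of the change by deprivation with that by the drug was -0.58 at 200 µM (simulated mean -0.09, range -0.42 to 0.31) and -0.20 at 100 µM (mean -0.07, range -0.40 to 0.27). The covariance was -0.314 (simulated mean -0.016, range -0.089 to 0.055) and -0.061 (mean -0.011, range -0.079 to 0.052). Both values at 100 µM thus lay within the simulated range, and both at 200 µM outside it. Without GD replicate 3 the share undone at 100 µM was -0.8%, so its direction rests on that library; it was 8.4% without GD replicate 2, 7.4% without 100 µM replicate 1 and 1.8% without 100 µM replicate 2. The 1014 genes became 645 without GD replicate 1 and 637 without 100 µM replicate 3. Without GD replicate 1, 2 or 3 or 100 µM replicate 1 or 3, the 332 genes moved further at 100 µM became 176, 164, 867, 180 or 211, and the 412 at 200 µM became 663 without GD replicate 3.

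Many genes changed against GD at both doses. Both contrasts use the same GD libraries, so chance error in these adds to the overlap, which the values for independent lists leave out. Of the genes changed against GD, 1127 changed in the same direction at both doses, 731 upward and 396 downward, where independent lists would share 296 and 76.7, and 62 changed in opposite directions. With median-of-ratios scaling the balance turned, to 659 shared rises and 906 shared falls (226 and 306 for independent lists). Pla2g2a, Nos2, Cxcl12 and Acta2 were among the shared rises, and Mlana, Lamp1, Gabarapl1 and Bag3 among the shared falls. The correlation of the changes across genes was 0.57, within the range of the simulations without a drug effect (mean 0.50, range -0.16 to 0.94). The covariance was 0.084, above their range (mean 0.012, range -0.003 to 0.027). Of 5758 genes changed at either dose, 3928 (68.2%) changed in the same direction and further at 200 µM, and 3507 differed between doses by test. More genes were called at 200 µM (5350) than at 100 µM (1597), so the set is largely chosen for its change at 200 µM and the share is partly built in. The simulations held 0.13 such genes in mean, too few to set beside it. The overlap was 742 without GD replicate 1.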

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

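The tests in this part on the scaling, short transcripts, serum, shared libraries, leukocytes and the return toward control were chosen after the results were seen; those on other splits of the libraries and on the difference between doses were planned.

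A set of 62 genes changed in opposite directions at 100 µM and at 200 µM against GD. Of these, 18 were higher at 100 µM and lower at 200 µM, and 44 the other way round. All 62 also differed between the doses by limma. Opposite changes against the same GD libraries nearly ensure this, so the test between doses adds no separate support. After median-of-ratios scaling 78 genes changed in opposite directions, counted without the test between doses. Of the genes named by rule, 9 are among the 62, and the log2 difference between 200 and 100 µM is given for each. Cpt1a and Acaa2, both of fatty acid oxidation, were lower than GD at 100 µM and higher at 200 µM, Cpt1a at -0.81 and 0.65 (difference 1.46) and Acaa2 at -0.41 and 1.01 (difference 1.43). The glycolysis genes Gpi, at -0.28 and 0.42 (difference 0.70), and Gapdh, at -0.19 and 0.29 (difference 0.48), moved the same way, as did the actin-severing protein gene Gsn, at -0.51 and 0.57 (difference 1.08), and the heart transcription factor gene Hand2, at -0.38 and 0.23 (difference 0.61). Fez1, at 0.79 and -1.83 (difference -2.62), the ER translocon gene Sec61b, at 0.29 and -0.37 (difference -0.66), and the respiratory chain gene Uqcrq, at 0.27 and -0.15 (difference -0.42), went the other way. Several of the 100 µM calls are weak: Acaa2 passed at an adjusted p of 0.0461. Gapdh did not pass after median-of-ratios scaling (0.127), without trend (0.0807) or with the 2 groups alone (0.0793), nor Gpi with the 2 groups alone (0.0673) or Gsn with no filter (0.0661). Leaving out 1 library ended the 100 µM call of Gsn (GD replicate 1 or 2, 100 µM replicate 1 or 3; adjusted p up to 0.0856) and of Gpi (100 µM replicate 1; 0.0678).

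More genes were lower than higher after deprivation. The larger share of ribosomal protein and ferritin genes accounts for part of it: without them the median log2 fold change of the other genes moved from -0.65 to -0.33 (-0.37 to -0.27 without 1 library), with 3018 genes higher and 6371 lower, so it is not the whole cause. Short transcripts taking more of GD libraries would raise respiratory chain genes, also short and abundant, with the ribosomal protein genes, but the upper quartile of the former was -0.24 and the lower quartile of the latter 0.66. As respiratory chain genes lay above the median gene, that argues against this as the whole cause only. A change in serum cannot be told apart from glucose, since 0 of 9 deprived libraries have a serum label, and TPM hold no measure of total RNA per cell, so the fall of most genes may be relative.

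ER chaperone genes fell below the GD level at 200 µM, several of them, in TPM as deposited, to or below control. A general return toward control would undo their rise by as much as that of other genes that rose as far, but the median share undone was 122.2%, against 15.7 to 56.0% in the central 95% of random sets matched on the size of the rise. Those sets hold genes drawn singly, while genes of a list vary together, so the range is narrower than one for lists. The share undone was not computed after median-of-ratios scaling, which moved the list's median rise in GD from 0.89 to 1.65. The test against a general return thus holds only for TPM as deposited. Against GD the list's median log2 fold change was -0.94 as deposited and -1.13 after that scaling, where the median of all genes was 0.14 and -0.01. The list thus lay below the median gene under both. However, that scaling lowers changes in this contrast in general, so it could only deepen the fall and cannot test scaling as its source. The shared GD libraries are not the source of the fall, as the list's median was -0.78 between the doses. A specific loss of the ER folding program at 200 µM may therefore be set up as a hypothesis, found and tested on the same data; whether it is due to SGLT2, another target or toxicity at this dose was not tested.

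Inflammation genes rose with the drug, further at 200 µM. RNA from leukocytes would bring their abundant transcripts, but of Ptprc, Laptm5, Tyrobp, Cd74 and Lyz2 the highest mean at 200 µM was 0.24 TPM, in Cd74. Cd14, a leukocyte marker that these cells also held in control (34.1 ± 1.31 TPM), was at 5.59 ± 1.52 in GD and 12.8 ± 2.31 at 200 µM. The shared GD libraries are not the source of the further rise at 200 µM, as the list's median was 0.86 between the doses. That contrast cannot weigh them for the rise at 100 µM against GD (median 0.77). A response of the cells to the drug may be set up as a hypothesis; an impurity such as endotoxin in the drug solution, or its solvent, was not tested and stays open.

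Splitting the 6 libraries of a comparison in other ways gave fewer changed genes, but 3 against 3 libraries make 10 splits, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many. The real count and the highest of the others were 10042 and 0 for GD against control, 1597 and 102 for 100 µM against GD, 5350 and 0 for 200 µM against GD, 4159 and 1 between the doses, 9937 and 2 for 100 µM against control, and 9379 and 1 for 200 µM against control.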

How the results depend on the processing

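The alternatives were planned except median-of-ratios scaling and leaving out ribosomal protein and ferritin genes, which were chosen after the data were seen. Over 309 named gene comparisons and the alternatives that were run on single genes, which leave out the other thresholds and list tests, 5113 outcomes kept direction and side of the threshold, 28 gained a call, 95 lost it (51 by leaving out 1 library) and 3 reversed. Those counted as reversed were Becn1 in GD against control, by construction of the scaling. It was at 0.15 with quantile normalization (adjusted p = 0.0287) and 0.39 with median-of-ratios scaling (2.02e-05). Without ribosomal protein and ferritin genes it was at 0.05 and did not pass (0.547), so there only the sign turned and the call was lost.

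Quantile normalization gave 596 and 741 genes moved further at 100 and 200 µM, array weights, whose estimation stopped before convergence, 3679 genes for 100 µM against GD and a fit of the 2 groups alone 707. The cause was not tested. With a 2-fold minimum the counts were 4657 for GD against control, 75 for 100 µM against GD, 728 for 200 µM against GD, 475 between doses and 4453 and 3231 for the doses against control; reversal was 32 and 568, overlap 54, dose order 636 and genes moved further 8 and 12. At an adjusted p under 0.01, 675 genes were called for 100 µM against GD and 2609 between doses, reversal at 100 µM was 419, overlap 497 and genes moved further 104 and 198. These minima are stricter by construction. Median-of-ratios scaling gave 28.5% undone at 200 µM and 506 genes moved further at 100 µM, and leaving out ribosomal protein and ferritin genes 28.7% undone at 200 µM; the cause was not tested. With an estimated correlation, camera called 0 lists in each of the 4 main comparisons, against 17, 11, 13 and 14 with the preset and, by fry, 29, 4, 20 and 19; at an unadjusted p under 0.05 the estimated correlation gave 4, 4, 3 and 2.

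Leaving out 1 library gave 9685 to 9938 genes for GD against control, 9499 to 9723 and 8796 to 9021 for 100 and 200 µM against control, 1005 to 2476 for 100 µM against GD, 4374 to 5360 for 200 µM against GD and 3086 to 3852 between doses. Reversal was 637 to 1142 at 100 µM and 3568 to 4488 at 200 µM, the share undone -0.8 to 8.4% and 20.4 to 28%, genes moved further 164 to 867 and 276 to 663, overlap 742 to 1573 and dose order 3360 to 4196. Lists called were 16 to 17, 8 to 12, 13 to 15 and 13 to 15. Fewer libraries lower the power of each test, yet several counts rose, such as 100 µM against GD, overlap and genes moved further without GD replicate 3 (2476, 1573, 867 and 663), and reversal at 200 µM (4488) and dose order (4196) without GD replicate 2.

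With replicate number as an added term the counts were 10105, 1624, 5474, 4301, 9988 and 9389 in the order of the comparisons. At 100 µM against GD it ended the call of Egr1 (adjusted p = 0.0534) and gave one to Mcm7 (0.0446). Whether libraries of different groups with the same number are paired is not settled by the labels or by their residuals. Residuals of same-number libraries correlated at -0.094 to 0.212 over 18 pairs (median 0.027), 3 of them above 0.1. Over the 36 pairs with different numbers the range was -0.218 to 0.222 (median -0.001), also with 3 above 0.1. Of the 12 libraries, 7 correlated best with a library of their own number. The alternatives meant for counts were run as their counterparts for normalized values, and the one for a table with both units was not run. Depth is unknown, so the precision of low values cannot be given.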

Other observations

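The lists of this part were fixed in advance, while the matched random sets for the share undone were chosen after the results were seen.

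Other metabolic and stress genes moved in lists that did not pass by camera against GD. At 200 µM against GD, 11 of 23 fatty acid oxidation genes rose and 3 fell (camera adjusted p = 0.314, fry 0.00285; 10 and 7 after median-of-ratios scaling), Acadvl, an enzyme for long-chain fatty acids, from 2.01 ± 0.29 to 10.8 ± 0.99 TPM (SD, n = 3), while at 100 µM 5 fell and 1 rose (0.101), Acadl from 109 ± 10.4 to 59.7 ± 1.08 TPM. Of 13 fatty acid synthesis genes 8 rose and 2 fell at 200 µM (0.37, fry 0.0303; 6 and 2 after that scaling), Acss2, which activates acetate, from 4.86 ± 0.30 to 17.9 ± 3.69 TPM. Of 18 hypoxia genes 7 rose and 4 fell at 200 µM (0.764), and 4 and 5 after that scaling. Of 20 sodium-handling genes 5 rose and 4 fell at 200 µM (0.67), or 2 and 4 after that scaling, and 0 rose and 3 fell at 100 µM (0.176), or 1 and 3.

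Genes of growth arrest and cell death moved in lists that did not pass by camera. Bax, a promoter of mitochondrial cell death, rose from 184 ± 4.45 to 262 ± 17.8 TPM at 100 µM (log2 fold change 0.50), in an apoptosis and necroptosis list with 2 up and 1 down (adjusted p = 0.533). At 200 µM 11 of 30 of that list rose and 4 fell (15 and 4 adjusted over the list alone; 0.37, fry 0.00349; 7 and 5 after median-of-ratios scaling), Bcl2l11, a gene of the same family, from 4.72 ± 0.75 to 11.8 ± 1.04 TPM (1.16). Of 24 p53 targets 6 rose and 3 fell at 200 µM (0.764), or 5 and 7 after that scaling, with Btg2 at 1.34. Of 16 FOXO and atrophy genes 6 rose and 1 fell (0.456, fry 0.046). Cited2 rose from 24.8 ± 1.47 to 71.9 ± 8.12 TPM, while the muscle ubiquitin ligase gene Trim63, at 21.2 ± 0.54 TPM in control and 73.0 ± 6.23 in GD, was at 32.2 ± 2.89 TPM at 200 µM.

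The changes by deprivation were undone unevenly at 200 µM, in TPM as deposited. A uniform return toward control would keep the median share undone of each list within random sets matched on direction and size of the change, but 9 of 40 list sides with at least 5 members lay outside, 4 above and 5 below (11 at 100 µM), each after adjustment over the 40 sides. Above lay risen ER chaperones (122.2%), and fallen genes of the respiratory chain (63.6%, random 8.7 to 36.3%), inflammation (109.8%, random 1.4 to 49.7%) and interferon lists (107.1%, random 5.3 to 41.5%). Below lay risen ribosomal protein genes (7.8%, random 28.2 to 51.6%), fallen DNA replication (1.5%, random 16 to 33.6%) and mitosis genes (1.0%, random 18.3 to 34.1%), risen inflammation genes (-162.8%, moving further from control) and fallen ER genes (-38.2%, adjusted permutation p = 0.0036). For the other 8 sides the permutation p was 2e-04, the smallest that 10000 sets can give, and 0.001 adjusted. Fallen cholesterol genes (38.1%, adjusted p = 0.055), skeletal muscle genes (8.4%, 0.055), contractile genes (34.6%, 0.13) and matrix genes (32.6%, 0.16) were not outside by this permutation test.

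A candidate explanation is that 200 µM acted on separate programs rather than lessening the deprivation as a whole, since 9 list sides left the range of a uniform return toward control, risen ER chaperones with 122.2% undone among them. The test has limits. Genes of a list vary together, which random genes do not, so the ranges are too narrow for lists; the share undone shares GD libraries with the matching variable; and some sides depend on the scaling. After median-of-ratios scaling 34 of 62 respiratory chain genes were higher and 7 lower, against 3 and 51 as deposited. Interferon genes went from 4 risen and 13 fallen to 8 and 7, and the fallen ER genes from 8 to 4. The risen ER genes went from 20 to 26, and the list's median rise in GD from 0.89 to 1.65. Its median at 200 µM against GD moved less, from -0.94 to -1.13. The shares undone were not computed after that scaling, so a return of ER genes past control is shown only for TPM as deposited. The candidate explanation stays a hypothesis found and tested on the same data.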
